A study of Caenorhabditis elegans with 2 samples.

How the data were processed

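The series held ChIP-seq of ETS-4 tagged with GFP and FLAG in late embryos of C. elegans strain OP509, with 2 biological replicates and 1 group per the labels. Each replicate had a list of regions in the ce10 and in the ce11 build, and the series had a pooled list and an IDR list in each. Per the readme texts deposited with the samples, each replicate list was made from that replicate's alignments and a control file. The pooled list was made from both replicates' alignments and the control, and the IDR list from the replicate and pooled lists. IDR keeps regions whose rank is reproducible between replicates. The replicate and pooled lists kept weak regions as input for this step. The aligner, peak caller, IDR threshold and their versions are not given in the sources used here, and the control library was not used here.

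The signal value of each region is the one the authors deposited, in column 7 of the narrowPeak layout, and was used to rank regions within a list. The significance of each region is the −log10 q that the authors deposited in column 9. No read counts were given, so the depth of each library is unknown and no counting interval on signal can be had. In the IDR list, −log10 q ran from 2.39 to 3.29 and signal from 71.1 to 1137.1. Each of the 1106 IDR regions was in the pooled list with the same signal, and 1106 pooled regions had a signal at or above the lowest of them, so the IDR list was the top of the pooled list by signal. Of the IDR regions, 1105 were distinct intervals, since 1 interval was listed with 2 summits. Of the 1106, 865 had the commonest width (404 bp) with the summit at the centre.

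All ce11 regions lay within the chromosome lengths of the WBcel235 reference (ce11), and sequence and genes were taken from it with Ensembl release 115. No ce10 reference was used, so the ce10 lists served for counts, overlaps and correlations. A promoter window ran from 1000 bp upstream to 200 bp downstream of each of 29314 starts of protein-coding transcripts, and a gene carried a peak when an IDR summit lay in a window of it. The background was 6130 low-ranked regions, which are pooled regions under the median signal (31.2) that overlap no IDR peak. They passed the same calling and mapping steps. Shares were compared with two-sided Fisher's exact tests, with odds ratios and 95% Woolf intervals, and single shares have 95% Wilson intervals that cover counting error only. Exact binomial tests compared shares with chromosome length. Of the fixed list members, atf-5 (stress response) and elt-5 (epidermis) were not found by name among the protein-coding genes and were left out. Families of tests were adjusted by Benjamini-Hochberg.

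Replicates were compared by the share of overlapping regions among the 1106 of highest signal, with 100000 circular shifts, and by Spearman and Pearson correlations with 100000 permutations. Motifs, fixed as 16 consensus sequences, and all 2080 6-mers with reverse complements merged were searched within 100 bp of each summit on both strands. GC matching drew low-ranked windows in steps of 2% GC. The 20 gene lists and 16 motifs, the tests and the alternatives were written before the data were examined, except for those named as added afterwards. The named genes follow a rule also fixed then. It took the 20 promoter peaks of highest signal, each named by the nearest start, and the 5 highest peaks outside promoter windows. It took all members of the lists of ETS-4 literature and ETS family genes, up to 4 members with a peak in each other list, the 10 6-mers of lowest p and the 16 motifs.

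Alternatives were the top 1106 regions of each replicate alone, the upper 50% of IDR peaks, the top of the pooled list, the ce10 lists, a reciprocal overlap of 50%, summits within 100 bp, and fewer or more top regions. Further alternatives were promoter windows of 500/100 and 2000/200 bp, the nearest start within 5 kb, motif windows of 50 and 250 bp, flanks 400 to 600 bp from the summit, promoter summits alone, all 11076 pooled regions outside the IDR peaks, and windows of 20 and 80 kb at ets-4. Added after the data were seen were the GC-matched background, the 100 peaks of highest signal, the results without chromosome III, the tests of single chromosomes other than X, of places within gene models and of noncoding RNA genes, and the split of X by signal.

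The scripts were tested on simulated data. For the motif comparison, CCGGAAGT placed in 200 of 1106 low-ranked windows was called, and its 3 6-mers had the lowest p of 2080. With nothing placed, 0 of 16 motifs and 0 of 2080 6-mers were called. Both groups of windows were drawn at random from the low-ranked regions. This check therefore does not cover calls that follow a difference in GC content or promoter share. For the gene list comparison, a list given 12 added genes was called in 100 of 100 draws, and some list was called in 4 of 100 draws with nothing added. For the replicate overlap, 4 of 100 unrelated region sets had a shift p under 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.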

Results

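Chromatin immunoprecipitation sequencing (ChIP-seq) was carried out on whole late embryos of the nematode Caenorhabditis elegans, collected 5 hours after synchronization by egg bleaching. The embryos came from strain OP509, which carries an integrated transgene of ETS-4, a transcription factor of the ETS family, fused at its C-terminus to GFP and FLAG tags. Chromatin was sheared by sonication and precipitated with an anti-GFP antibody. The 2 samples were biological replicates of this 1 group, so the design held no comparison between conditions. The questions it could answer were where the tagged protein was found along the genome, near which genes, at which sequences and how closely the replicates matched. Regions were given as peak lists without read counts, so the depth of each library is unknown. The replicate 1 list held 15619 regions and the replicate 2 list 14622 regions in the ce11 build, weak regions included. The list from both replicates pooled held 12348 regions. The list of reproducible peaks, selected by the irreproducible discovery rate (IDR) and called IDR peaks here, held 1106. All coordinates are 1-based ce11 positions.

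The IDR peaks lay mainly upstream of protein-coding genes. The peak of highest signal (1137.1) had its summit at III:8043961, in an intergenic stretch 526 bp from the nearest start of K12H4.5. It was followed by a peak in an intron at III:3500039 (signal 742.9), 982 bp from the start of M01F1.9. The third lay at III:5172675 (727.2), 45 bp from the start of K10D2.5 and within the promoter windows of prp-19, a splicing factor, and emb-1. The signal value is the peak caller's own value per region and was used here to rank regions within a list. Of the 1106 peaks, 763 (69.0%, 95% Wilson interval 66.2 to 71.6%) had their summit in a promoter window, from 1000 bp upstream to 200 bp downstream of a protein-coding transcript start. Low-ranked regions, taken from the lower 50% of the pooled list by signal and overlapping no IDR peak, had 33.2% of 6130 summits there (odds ratio 4.48, 95% interval 3.90 to 5.15, two-sided Fisher's exact test, p = 1.106e-109). The windows covered 26.1% of the genome.

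The place of the summits within gene models differed from that of the low-ranked regions. Intergenic positions held 74.6% of IDR summits and 2454 of the 6130 low-ranked summits (odds ratio 4.4, 95% interval 3.81 to 5.08, adjusted exact p = 3.118e-101). Introns held 19.5% against 33.8% (odds ratio 0.48, adjusted exact p = 6.839e-22). Coding exons held 6 of the 1106 IDR summits (0.54%) and 18.2% of low-ranked summits (odds ratio 0.025, 95% interval 0.011 to 0.055, adjusted exact p = 5.302e-77). With replicate 2 left out, coding exons held 13 of 1106 summits (odds ratio 0.053). Summits in 5' UTRs were more frequent among IDR peaks (4.52% against 2.51%, adjusted exact p = 5.932e-04), and those in 3' UTRs were less frequent (0.72% against 5.24%, adjusted p = 8.144e-15). These are two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 6 kinds of place, added after the data were seen. The median distance to the nearest start was 324.5 bp for IDR summits and 1110 bp for low-ranked summits.

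Peaks at promoters also had a higher median signal, with widely overlapping quartiles. Among the IDR peaks, the 763 with promoter summits had a median signal of 109.8 (quartiles 84.5 and 156.5), and the other 343 had a median of 97.2 (quartiles 81.6 and 124.4). The difference of 12.6 gave p = 1.3e-04 in a two-sided permutation test with 100000 resamples. Regions are not independent replicates, so this and the other tests across regions describe these lists and not the spread between animals.

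The 20 promoter peaks of highest signal ranged from 309.2 to 1137.1, and 11 of them were on chromosome III. The peak at III:5349456 (532.6) lay 55 bp from the start of thoc-5, a component of the THO complex of messenger RNA export. The peak at III:5308432 (501.0) lay 164 bp from mog-3. The remaining peaks on III were nearest to C45G9.2 (III:5068995, 500.1), tasp-1 (III:10759254, 434.8), cux-7 (III:7520846, 401.4), F01F1.3 (III:5871956, 321.3), tag-340 (III:4899905, 318.3) and rpl-3, a protein of the large ribosomal subunit (III:3867585, 314.8). On other chromosomes, the peak at I:5807471 (389.6) stood 180 bp from the start of vps-51 and shared its window with lin-35, the worm's Rb protein. A peak at IV:3050659 (365.0) lay 555 bp from eel-1, a ubiquitin ligase gene. Further peaks were nearest to F56G4.6 (345.6), jmjd-1.2, a histone demethylase (337.6), chaf-2, a chromatin assembly factor (326.7), T07F10.3 (326.3), Y92H12BR.2 (311.1), Y41D4A.4 (309.3) and Y50D4C.5 (309.2). Of the peaks on III, those at K10D2.5, thoc-5, mog-3, C45G9.2 and F01F1.3 lay between 5 and 6 Mb, and the others lay outside that stretch. Extra copies of that stretch in the strain, weighed below as a possible cause of its many peaks, may also raise the signal there. Whether they did was not tested. In 12 of the 20 the summit lay in the promoter windows of more than 1 gene, so the nearest gene need not be the gene concerned. In the separate lists the signals at these 20 peaks ran from 131.9 to 593.9 in replicate 1 and from 141.2 to 545.5 in replicate 2.

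Outside promoter windows, the highest peak lay in an intron of frm-7 at V:12303632 (signal 296.1). The next was intergenic at I:933517 (280.7), 4966 bp from the nearest start, of nas-30. Summits in introns of klp-6, a kinesin gene (III:5031492, 272.3), and of Y56A3A.7 (III:11946547, 268.8) followed, then an intergenic summit at V:14055232 (261.0), 2608 bp from the start of F58D12.3. The klp-6 summit also lay between 5 and 6 Mb on III.

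The replicates gave largely the same strong regions. Of replicate 1's 1106 regions of highest signal, 809 (73.1%, 95% Wilson interval 70.5 to 75.7%) overlapped 1 of replicate 2's top 1106 by at least 1 bp. Random circular shifts along the chromosomes gave 0.91% on average, and none of 100000 reached the observed share (one-sided permutation test, p = 1e-05, the smallest they can give). Overlap was 60% of the top 50 regions, 62% of the top 100 and 68% of the top 200, and fell from 74.4% of the top 1000 to 50.7% of the top 5000 and 43.6% of the top 10000. Across the 1105 IDR peaks with a region in both lists, the replicates' signals had a Spearman rho of 0.62 and a Pearson r of 0.69 on log2 signal (each p = 1e-05 in a permutation test, the smallest possible). This correlation is across peaks, not across samples. The peaks were the top of the pooled list by signal, and that list was made from both replicates. After removing the median difference, 76.2% of peaks differed by less than 1.5-fold between replicates.

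**Figure D1:**
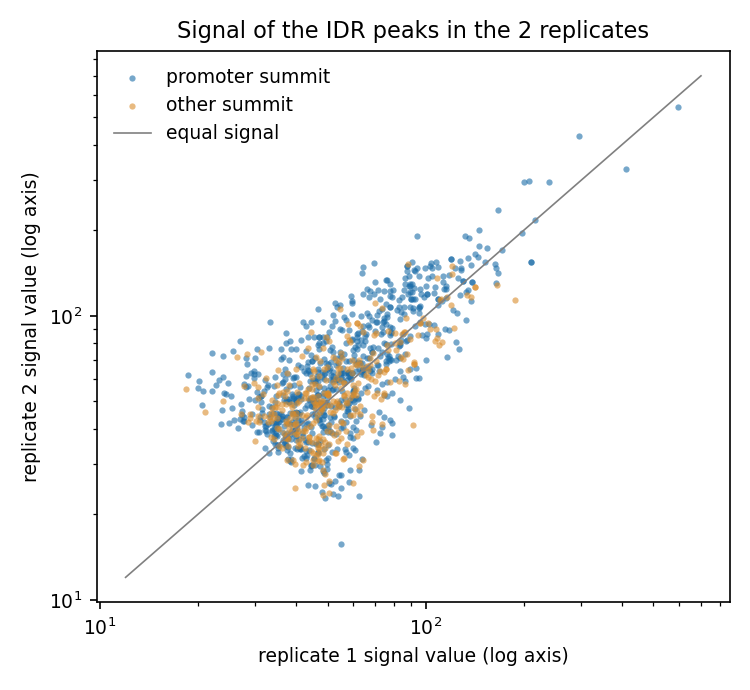
Signal value of each IDR peak in replicate 1 (horizontal log axis) and replicate 2 (vertical log axis), with 1 point per peak, blue for promoter summits and orange for other summits, and a line of equal signal. The points follow the line with a Spearman rho of 0.62 over 1105 peaks.

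Peaks were unevenly spread over the chromosomes. Chromosome III held 256 of the 1106 peaks (23.1%, 95% Wilson interval 20.8 to 25.7%) on 13.7% of the genome, or 18.6 per Mb (two-sided exact binomial test, adjusted p = 2.287e-16 over 6 chromosomes). Of the 6130 low-ranked regions, 1010 were on III (odds ratio 1.53, 95% interval 1.31 to 1.78, Fisher's exact test, p = 1.83e-07). Each chromosome held from 16.3 to 17.1% of the low-ranked regions, although chromosome lengths ran from 13.7 to 20.9% of the genome. This background therefore did not follow length, and its odds ratios for single chromosomes do not compare with a genomic expectation. Chromosomes IV and V held fewer peaks than their length would give, with 141 against 193.0 (adjusted exact p = 4.353e-05) and 152 against 230.8 (adjusted p = 3.412e-09). Chromosome I held 199 against 166.2 (adjusted exact p = 0.0106). Chromosome II held 182 against 168.5 (adjusted exact p = 0.259). The tests of chromosomes other than X were added after the counts were seen. The bin from 5 to 6 Mb on III held 60 IDR peaks, where the median of the 103 bins of 1 Mb was 10. It held 60 of the top 1106 regions of replicate 1 and 63 of those of replicate 2. The next highest count, 32 IDR peaks, was in the adjacent bin from 4 to 5 Mb on III.

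**Figure D2:**
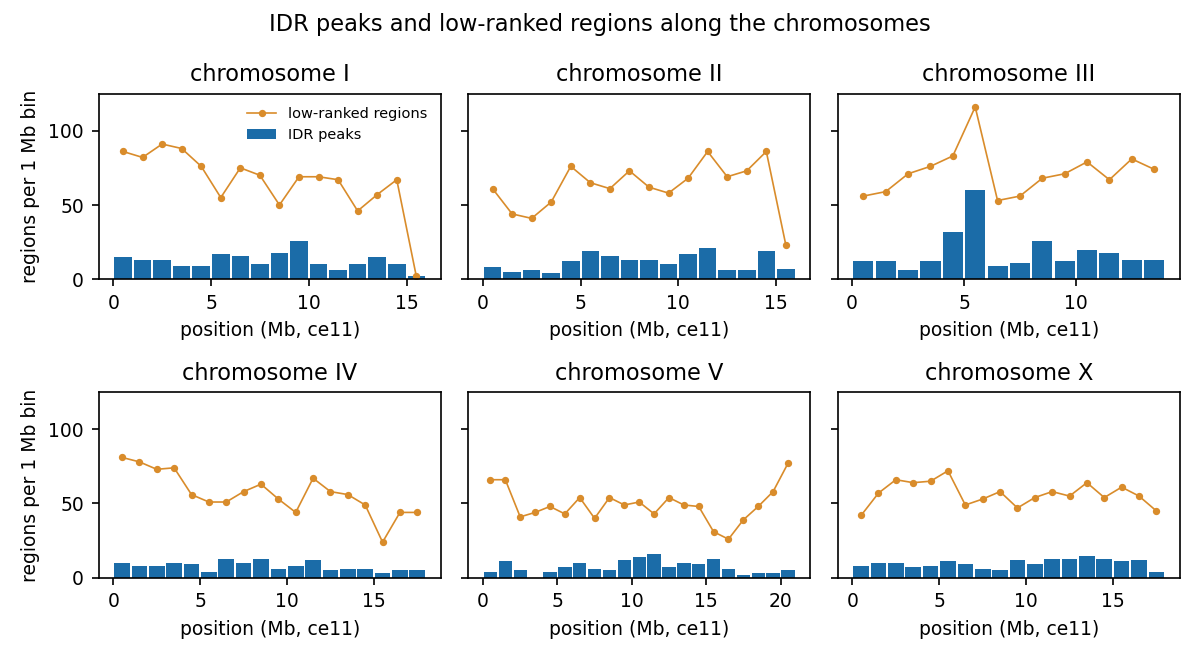
Number of IDR peaks (blue bars) and low-ranked regions (orange points) in each 1 Mb bin along the 6 chromosomes, with position in Mb (ce11) on the horizontal axis and regions per bin on the vertical axis. The tallest bar, 60 peaks, stands between 5 and 6 Mb on chromosome III; the last bin of each chromosome is shorter than 1 Mb.

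Chromosome X held 176 peaks (15.9%, 95% Wilson interval 13.9 to 18.2%), against 16.6% of low-ranked regions (odds ratio 0.95, 95% interval 0.80 to 1.13, Fisher's exact test, p = 0.598) and 17.7% of the genome's length (exact binomial test, p = 0.134). The low-ranked regions were spread almost evenly over the 6 chromosomes, so only the test against length compares X with a genomic expectation. Stronger peaks were scarcer on X. Of the upper 553 peaks by signal, 13.2% were on X, and of the lower 553, 18.6% (odds ratio 0.66, 95% interval 0.48 to 0.92, Fisher's exact test, p = 0.017). Among promoter summits the shares were 8.50% and 15.7% (odds ratio 0.50, 95% interval 0.32 to 0.78, exact p = 0.00235). Among other summits they were 38 of 141 and 48 of 202 (exact p = 0.528). This split by signal was chosen after the data were seen. On the autosomes, 569 of 930 IDR summits (61.2%, 95% Wilson interval 58.0 to 64.3%) fell in the central 50% of the chromosome. Low-ranked summits had 49.5% there (odds ratio 1.61, 95% interval 1.39 to 1.85, Fisher's exact test, p = 4.823e-11), and an exact binomial test against 50% gave p = 9.38e-12.

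The sequence at the summits was richer in GAGAGA repeats and not in the sites that ETS factors bind. GAGAGA, on either strand within 100 bp, was present at 436 of 1106 IDR summits (39.4%) and at 15.7% of low-ranked summits (odds ratio 3.49, 95% interval 3.04 to 4.01, adjusted exact p = 3.134e-64). Against low-ranked regions matched on GC content, a background added after the data were seen, the odds ratio of GAGAGA fell to 2.12 (95% interval 1.76 to 2.55). The ETS core GGAA was present at 81.6% against 86.8% (odds ratio 0.68, 95% interval 0.57 to 0.80, adjusted exact p = 3.698e-05). The longer ETS site CCGGAA was present at 64 IDR summits (5.79%) against 7.80% (odds ratio 0.73, 95% interval 0.55 to 0.95, adjusted exact p = 0.0366). The full consensus CCGGAAGT was at 2 IDR summits (0.18%) against 0.38% (odds ratio 0.48, 95% interval 0.11 to 2.04, adjusted exact p = 0.472). With replicate 1 left out CCGGAAGT was at 3 summits (odds ratio 0.72), and with replicate 2 left out at 1 (odds ratio 0.24). The tests were two-sided Fisher's exact tests adjusted over 16 motifs. The lower share of CCGGAA lost its call in replicate 1's regions alone (odds ratio 0.74, adjusted exact p = 0.051), and in 5 other settings fixed in advance. Among the 100 IDR peaks of highest signal, a setting added after the data were seen, CCGGAA had an odds ratio of 1.17 (95% interval 0.59 to 2.33), and GAGAGA had 1.60 (95% interval 1.00 to 2.57, adjusted exact p = 0.424).

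Of the 16 motifs, 2 were more frequent and 6 less frequent at IDR summits. The other more frequent motif was the SP1/KLF box CCGCCC (13.3% against 6.64%, odds ratio 2.16, adjusted exact p = 6.852e-12). Against low-ranked regions matched on GC content its odds ratio was 1.15 (adjusted exact p = 0.405). The odds ratio of CCGCCC was 4.69 against the flanks of the same peaks and 1.06 in the 100 IDR peaks of highest signal. The less frequent motifs, besides both ETS forms, were the GATA site TGATAA (7.32% against 17.3%, odds ratio 0.38, adjusted exact p = 1.211e-18, with odds ratios of 0.61 against the GC-matched regions, 0.20 within 50 bp and 0.68 within 250 bp), CGGAT, the core of SPDEF-type ETS sites (153 of 1106 against 1105 of 6130, odds ratio 0.73, adjusted p = 0.00174), the HOX/TALE site TGATTGAT (0.36% against 1.42%, odds ratio 0.25, adjusted p = 0.00413) and the splice acceptor TTTTCAG (110 of 1106 against 990 of 6130, odds ratio 0.57, adjusted p = 1.702e-07). TGATTGAT and TTTTCAG no longer passed against the GC-matched regions (exact tests, adjusted p = 0.208 and 0.215), within 250 bp (0.0944 and 0.232) or in the upper 50% of peaks (0.0642 and 0.064). CGGAT no longer passed among promoter summits alone (odds ratio 0.77, adjusted exact p = 0.0584). Neither CCGGATGT (0.09% against 0.28%, adjusted exact p = 0.456) nor the FOX, bZIP AP-1, C/EBP, E-box, T-box and nuclear receptor sites passed the threshold, with adjusted p from 0.248 to 0.568. The nuclear receptor site AGGTCA (odds ratio 0.82) passed as less frequent with replicate 1 left out (odds ratio 0.62, adjusted exact p = 0.012), within 50 bp (0.56, adjusted p = 0.044) and within 250 bp (0.69, adjusted p = 0.00188). The T-box site fell from 2 to 1 summit with replicate 1 left out. IDR summits had a mean GC content of 45.01% (SD 7.69), low-ranked summits 37.9% (SD 8.53) and the flanks of the IDR peaks 36.6% (SD 7.24).

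**Figure D3:**
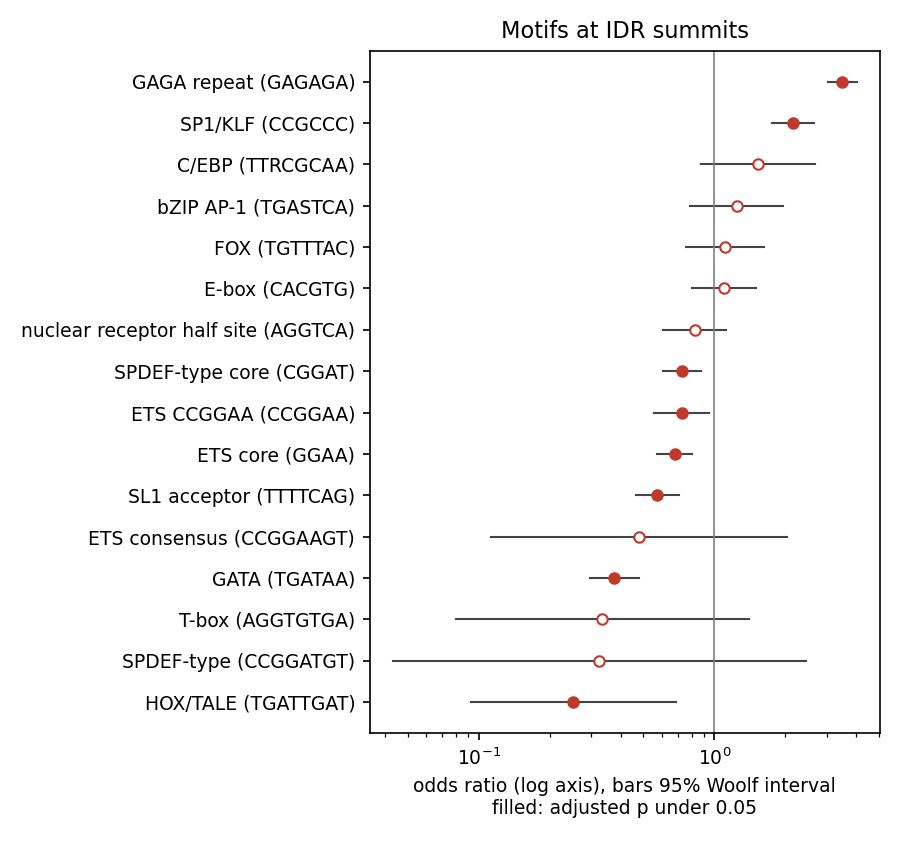
Odds ratio (log axis) of each of 16 motifs within 100 bp of the summit, IDR peaks against low-ranked regions, with bars for the 95% interval and filled points where the adjusted p is under 0.05. GAGAGA (3.49) and CCGCCC (2.16) lie above 1, and the ETS forms GGAA (0.68) and CCGGAA (0.73) lie below it.

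The search of all 2080 6-mers, against low-ranked regions with the same proportion of promoter summits, also gave GAGA-type and CG-containing words. The 10 with the lowest p were AGAGAC (31.2% against 10.2%), CGAGAG (27.6% against 8.18%), GAGAGA (39.4% against 17.3%), AGCGCG (17.8% against 4.21%), GAGCGC (19.5% against 5.23%), CGTCTC (26.7% against 9.64%), AGAGAG (33.3% against 14.3%), ACGCAG (22.4% against 7.13%), AGAGCG (20.5% against 6.01%) and CGCGCA (18.5% against 4.92%). Their odds ratios ran from 3.00 for AGAGAG to 4.93 for AGCGCG, and AGAGAC had the lowest adjusted p (8.334e-51, Fisher's exact test). In all, 551 6-mers were more frequent and 514 less frequent. This background was not matched on GC content, which averaged 45.01% at IDR summits and 37.9% at all low-ranked summits. Base composition alone can therefore move many of these words, the CG-containing ones among them. Some words of both types also overlap. AGAGAC, GAGACG (the reverse complement of CGTCTC), AGACGC, GACGCA, ACGCAG and CGCAGA are, in that order, successive parts of a longer sequence. All were more frequent at IDR summits, with odds ratios from 3.18 for CGCAGA to 4.00 for AGAGAC. They may therefore mark a longer motif rather than separate words, which was not tested. Of the 48 6-mers that contain GGAA, 5 were more frequent, 13 were less frequent and 30 did not pass. The highest-ranked of the 5 was CGGGAA, at rank 460 (12.4% against 7.88%, odds ratio 1.65, adjusted exact p = 7.453e-05).

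Ribosomal protein, stress response, respiratory chain and V-ATPase genes carried promoter peaks more often than other genes. Of 19865 protein-coding genes, 1066 (5.37%) had an IDR summit in a promoter window, and 4 of the 20 gene lists fixed in advance passed the test. Cytosolic ribosomal protein genes carried peaks at 31 of 79 members (39.2%, odds ratio 11.7, 95% interval 7.42 to 18.5, adjusted p = 3.991e-18, two-sided Fisher's exact test over 20 lists). The 31 genes shared 29 peaks, of which those at rpl-3 (signal 314.8), rpl-15 (307.5), rpl-43 (261.0) and rps-24 (259.0) were the highest. Another 40 members had a weaker pooled region only. When each peak was given only to the nearest start within 5 kb, 17 of 79 members had a peak (odds ratio 5.18).

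Stress response genes carried peaks at 11 of 27 members (40.7%, odds ratio 12.2, 95% interval 5.67 to 26.4, adjusted exact p = 5.945e-07). The highest were at the chaperone genes hsp-90 (234.7, summit in an intron at V:14685748), hsp-1 (185.8) and hsp-3 (175.7), and at the bZIP gene cebp-2 (117.9). hsp-16.2 and hsp-16.41 are divergently transcribed paralogs and shared 1 peak. With replicate 1 left out, 8 of 27 members had a peak (odds ratio 7.73). In the upper 50% of the peaks by signal the list no longer passed (odds ratio 5.67, adjusted exact p = 0.0536).

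Genes of the mitochondrial respiratory chain carried peaks at 12 of 39 members (30.8%, odds ratio 7.92, 95% interval 4.00 to 15.7, adjusted exact p = 3.628e-06), led by atp-5 (199.6), cox-6A (166.5), cox-6B (156.3) and cox-5B (129.5). V-ATPase genes carried peaks at 6 of 20 members (odds ratio 7.60, 95% interval 2.91 to 19.8, adjusted exact p = 0.00238), led by vha-12 (149.1), vha-13 (92.7), vha-4 (84.5) and vha-8 (78.1). In the upper 50% of peaks V-ATPase had 1 of 20 (odds ratio 1.71, adjusted exact p = 0.759), and with the nearest start within 5 kb 4 of 20 (odds ratio 4.68, adjusted p = 0.0841). With only the 5283 genes that had any pooled region in their window as background, ribosomal proteins (odds ratio 3.13, adjusted exact p = 1.455e-04) and stress response (odds ratio 3.65, adjusted p = 0.0263) passed, and the respiratory chain (odds ratio 2.81, adjusted p = 0.0582) and V-ATPase (odds ratio 2.98, adjusted p = 0.227) did not.

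**Figure D4:**
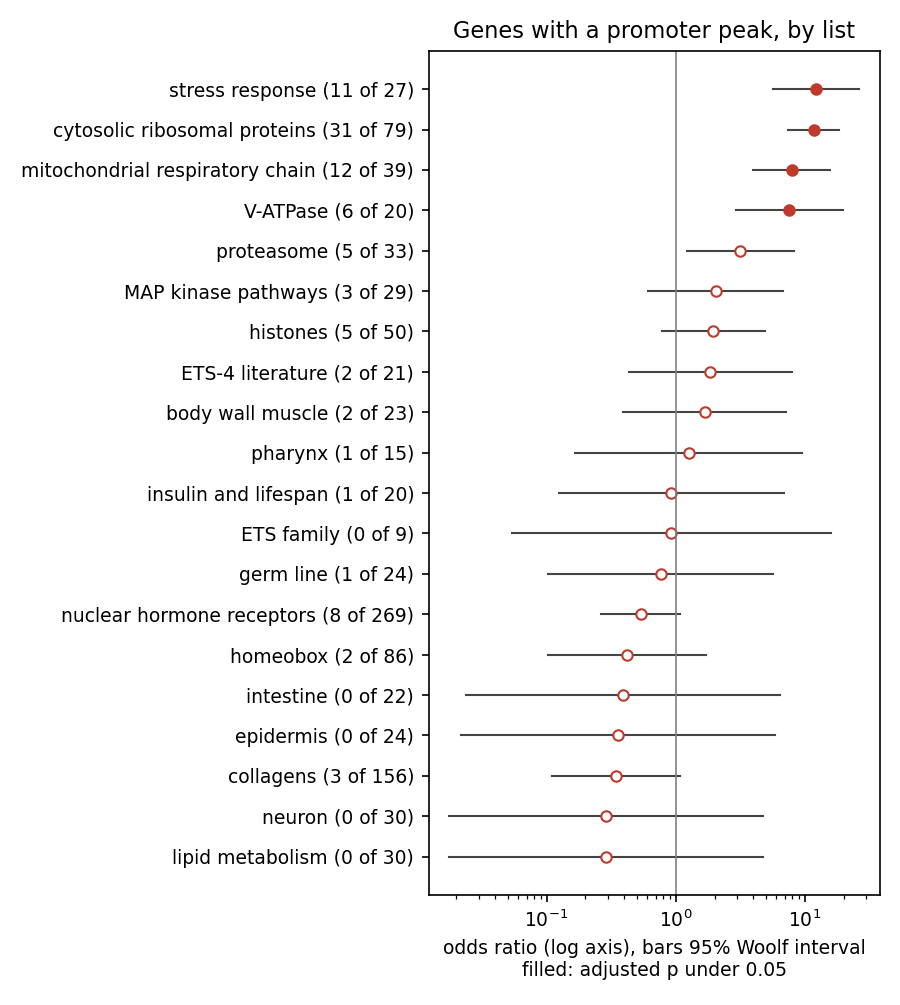
Odds ratio (log axis) of a gene having an IDR peak in its promoter window, for each of 20 gene lists against all other protein-coding genes, with bars for the 95% interval, filled points where the adjusted p is under 0.05, and members with a peak given in brackets. Stress response (12.2), cytosolic ribosomal proteins (11.7), respiratory chain (7.92) and V-ATPase (7.60) passed; lists with 0 members had 0.5 added to each cell.

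Genes that earlier work tied to ETS-4 did not differ from other genes past the threshold. Of 21 such genes, 2 had a peak (9.52%, against 5.36% of other genes, odds ratio 1.86, 95% interval 0.43 to 7.99, adjusted p = 0.582, Fisher's exact test). These were cebp-1, a bZIP factor gene of the axon regeneration pathway (X:1454534, signal 127.7, intergenic, 666 bp from its start), and kgb-1, a kinase gene of the JNK family (IV:410687, 133.2, intergenic, 652 bp from its start). The kgb-1 summit also lay in the window of T07A9.12. With windows of 500/100 bp, 0 of the 21 genes had a peak (odds ratio 0.53). The vitellogenin genes vit-1, vit-2, vit-3, vit-4, vit-5 and vit-6 had no pooled region in their windows, nor did rege-1, svh-1, ftn-1, ftn-2, pmk-3 or ets-4. The stages and tissues of the earlier work were not matched to the whole late embryos used here. A missing region therefore does not speak against a gene as a target at another stage or in another tissue. Weak pooled regions below the IDR list stood at mlk-1 (47.8), tdpt-1 (34.1), daf-16 (34.0), pqm-1 (31.6), svh-2 (28.6), klf-3 (27.1) and dlk-1 (24.6). The pooled list kept weak regions as input for IDR, with a lowest signal of 24.2 and a median of 31.2. Of all 19865 protein-coding genes, 5283 had a pooled region of any strength in their windows. Weak regions alone are therefore no evidence of binding. Of 9 ETS family genes none had an IDR peak (adjusted p = 1, exact test). With 5.37% of all genes carrying a peak, 9 genes are too few to show a lack of peaks. Weak regions stood at ets-6 (34.0) and ets-10 (31.0), and ets-4, ets-5, ets-7, ets-8, ets-9, lin-1 and ast-1 had none.

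Markers of tissues did not differ from other genes past the threshold either. None of 22 intestine, 30 neuron, 24 epidermis or 30 lipid metabolism genes had an IDR peak (adjusted exact p = 0.75, 0.582, 0.75 and 0.582). With 5.37% of all genes carrying a peak, lists this short could not have passed as less frequent even at 0 members. These values therefore cannot show a lack of peaks. Body wall muscle genes had 2 of 23, at unc-112 (106.9) and unc-60 (93.4), with 3 of 23 without replicate 1 and 4 of 23 without replicate 2 (odds ratio 3.93, adjusted exact p = 0.0784). The pharynx list had 1 of 15, at ceh-22 (81.3, summit in a coding exon), the germ line list 1 of 24, at cgh-1 (83.4), and the insulin and lifespan list 1 of 20, at rict-1 (126.3). MAP kinase genes had 3 of 29, which were kgb-1, cebp-1 and lin-45, a Raf kinase gene (132.8), with 5 of 29 without replicate 1 (odds ratio 3.81, adjusted exact p = 0.0632). Among large families, collagens had 3 of 156 (odds ratio 0.34, adjusted exact p = 0.166), at col-71 (199.6), col-2 (136.2) and col-38 (99.3), whose peak was shared with rpl-5. Nuclear hormone receptors had 8 of 269 (odds ratio 0.54, adjusted exact p = 0.285), led by nhr-142 (133.5), nhr-48 (114.6), nhr-255 (102.0) and nhr-47 (84.5). Homeobox genes had 2 of 86, at ceh-22 and ceh-38 (79.1). Histones had 5 of 50, of which his-67 and his-68 (138.2) and his-61 and his-62 (116.8) shared peaks and his-37 (186.4) had its own. The proteasome list had 5 of 33 (odds ratio 3.16, adjusted exact p = 0.12), led by rpn-3 (126.7), pbs-3 (116.8), pas-3 (114.8) and pas-1 (82.5). None of these lists passed the exact test after adjustment. Leaving out a replicate moved the pharynx, germ line, epidermis, lipid metabolism and homeobox lists by 1 gene each, and none of them then passed.

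No called region lay at the endogenous position of ets-4 (WBGene00017687, X:6518883-6522667), the gene copied in the transgene. The 40 kb window centred on it, X:6500775-6540775, held 0 pooled regions, so all windows on X held at least as many and no median signal could be compared. The median window on X held 4. In the replicate lists the window held 0 regions in replicate 1 and 1 in replicate 2. The gene lies in a gap of 80.8 kb between pooled summits, from X:6461673 to X:6542493, and 4 of the 2083 gaps on X were at least that long. With replicate 1 left out the gap was 53.2 kb (7 of 2463 gaps at least as long). With replicate 2 left out it was 66.6 kb (4 of 2688).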

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

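Beyond the IDR list, 172 pooled regions that overlap no IDR peak had a q value of 0.01 or lower, with signals from 65.0 to 71.1. They lie outside the set of peaks described in the results. Of these, 2 also overlapped regions at that q value in both replicate lists, and 59.9% had promoter summits.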

How the results depend on the processing

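The top of the pooled list was identical to the IDR list, so its 24 values test nothing. Of the other 398, 192 ask only if a named peak stayed among the peaks, and 174 did. Of the remaining 206, 172 kept their side of the threshold, and direction where there is one, or were counts of calls or peaks within 1.5 times the main count. The size of an effect can still move under these labels. The ce10 list held 1177 IDR peaks, and 1177 ce11 pooled regions reached its lowest signal (68.2), so the difference of 71 follows the signal limit. For the upper 50% of IDR peaks, 5 motifs passed in place of 8 and 2 gene lists in place of 4, with fewer peaks in the test. There, X held 13.2% and now passed (exact p = 0.0357), while odds ratios that no longer passed were 0.87 for CCGGAA, 0.25 for TGATTGAT, 0.74 for TTTTCAG, 5.67 for stress response and 1.71 for V-ATPase. CCGGAA also lost its call within 50 bp (0.72), against flanks (0.76), among promoter summits (0.83) and against all other pooled regions (0.76), and ran from 0.69 to 0.74 with either replicate left out. Its adjusted p over the alternatives other than the 100 highest peaks reached 0.644. With the 100 highest peaks 0 motifs passed. GGAA (0.69), GAGAGA (1.60) and CCGCCC (1.06) were among those that lost their calls. CCGGAA (1.17), CCGGAAGT (2.68) and TTTTCAG (1.06) reversed without passing. The GC-matched background left 5 motifs, without CCGCCC (1.15), TGATTGAT (0.36) and TTTTCAG (0.81), and lowered GAGAGA to 2.12. TGATTGAT (0.66) and TTTTCAG (0.90) also failed within 250 bp, and CGGAT (0.77) among promoter summits. The 100 highest peaks and the GC-matched background were chosen after seeing the data. With only genes that have a pooled region, 2 lists passed, and the respiratory chain (2.81) and V-ATPase (2.98) did not. Stress response kept its call at 7.73 with replicate 1 left out, ribosomal proteins at 5.18 with the nearest start within 5 kb, and coding exons at 13 summits (odds ratio 0.053) with replicate 2 left out. V-ATPase also failed with the nearest start within 5 kb (4.68). Beyond fewer peaks or genes tested, the cause was not tested. Of 64 named peaks, 61 were among replicate 2's top regions and 60 among replicate 1's. Read depth is unknown and its limits could not be measured. No paired analysis was possible because there is 1 group.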

Other observations

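Noncoding RNA genes, a group not described above and chosen after the data were seen, lay beside many peaks. IDR summits lay within 200 bp of a tRNA gene at 75 of 1106 peaks (6.78%) and low-ranked summits at 0.83% (odds ratio 8.67, 95% interval 6.04 to 12.5, adjusted p = 1.266e-29, Fisher's exact test over 7 classes). The count was 53 (odds ratio 5.77) with replicate 1 left out and 85 (9.92) with replicate 2 left out, and the odds ratio was 5.57 in the upper 50% of peaks. For snoRNA genes the shares were 3.80% and 0.29% (odds ratio 13.4, 95% interval 7.69 to 23.4, adjusted exact p = 5.473e-21). Among the 343 peaks outside promoter windows, 55 lay beside a tRNA gene and 27 beside a snoRNA gene, against 1.00% and 0.27% of low-ranked summits there. snRNA genes (0.63% against 0.10%, adjusted exact p = 0.00197) and lincRNA genes (0.81% against 0.29%, adjusted p = 0.0179) were also more frequent. piRNA genes (0.63% against 2.28%, adjusted p = 2.431e-04) and pseudogenes (0.72% against 2.09%, adjusted p = 0.00183) were less frequent, and miRNA genes did not differ past the threshold (adjusted p = 0.736). tRNA and snoRNA genes have near-identical copies, and how reads shared between copies were placed is not given in the sources used here.

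In the weighing that follows, the tests of the chance gap, of the single cluster and of extra copies were chosen after their results were seen, and the rule for the chance gap was also reworded then. Another 3 tests were left out for room: GAGAGA among promoter summits alone (odds ratio 2.09), chromosome III in each replicate alone (246 and 256 of the top 1106 regions) and promoter summits on X by signal (odds ratio 0.50). With 1 group, no biological explanation was tested.

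GAGAGA was enriched at summits and the ETS site was not. GC content alone does not account for this, since GAGAGA had an odds ratio of 2.12 (95% interval 1.76 to 2.55) against low-ranked regions of matched GC content, but this is below the unmatched 3.49, so part of the enrichment goes with GC content. Imprecise summits are argued against too, since CCGGAA within 250 bp had an odds ratio of 0.80 (95% interval 0.67 to 0.96). Dilution of strong peaks by weak ones stays open, because the odds ratio of CCGGAA in the 100 highest peaks was 1.17 with a 95% interval of 0.59 to 2.33. Binding that does not depend on an ETS site, or signal at active promoters that any tagged protein may give, is a hypothesis that these lists alone cannot separate. GAGAGA itself was at 250 of the 763 promoter summits (32.8%) and at 436 of all 1106 IDR summits (39.4%). The promoter summits are part of the 1106, so its share at the other summits was above 39.4%. Among the upper 553 peaks by signal it was at 187 (33.8%), so its share among the weaker peaks was also above 39.4%. Its odds ratio was 2.09 at promoter summits and 2.73 among the upper 553 peaks, both below 3.49.

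No pooled region lay in the 40 kb window at ets-4. Repeats are argued against, since 99.5% of the 32-mers of the gap occur once in the genome, as is a lack of promoters, since 59.8% of 40 kb windows on X held fewer protein-coding gene starts. A chance gap stays open. As few pooled regions were found in 3.55% of 40 kb windows on X and in 3.23% of 80 kb windows. The share was 6.07% with replicate 1 left out and 2.07% with replicate 2 left out. It was 15.02% for 20 kb windows, whose median was only 2 regions, so an empty window is a weak test there. A control library with the same transgene copies, or a filter at that locus, could also remove regions there, and neither was tested.

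Chromosome III held more IDR peaks than its length would give. The number of promoters is argued against, since 9.75% of genes on III and 4.90% of those on the other autosomes had a promoter peak (odds ratio 2.10, 95% interval 1.81 to 2.43). The cluster from 5 to 6 Mb was not the whole excess, since without it III held 18.7% of peaks (95% interval 16.49 to 21.22%) on 12.9% of the length. The adjacent bin from 4 to 5 Mb (32 peaks) stayed in that share, so how much of the rest flanks the cluster was not tested. For the cluster itself, extra copies of that region in the strain may be a cause. Low-ranked regions outside promoter windows numbered 68 there against a median of 38 in the other bins, and 1 other bin had as many. That median covers all chromosomes, and bins on III, the shortest chromosome, tend to hold more low-ranked regions. Counting all low-ranked regions, the bin held 116 and the other bins on III held 53 to 83. Those outside promoter windows were not compared within III. Pooled regions fell from 50 in the 100 kb before 6 Mb to 11 in the next 100 kb, but showed no such step at 5 Mb (32 before and 26 after), and read depth, which would test copy number, was not analysed here.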
